A study of Mus musculus with 10 samples.

How the data were processed

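The series holds RNA sequencing of mouse liver from animals carrying a floxed Arid1a allele, without (WT) or with (KO) the Alb-cre transgene, which expresses Cre recombinase in hepatocytes and deletes the floxed gene there. Per the labels, 6 libraries came from livers taken 40 h after partial hepatectomy, 3 WT and 3 KO, and 4 more came from livers before hepatectomy, 2 WT and 2 KO. The mice were of a mixed C57/B6 and 129 background at postnatal day 90. The 4 libraries from before hepatectomy were not analysed here, so the WT libraries at 40 h served as the only controls and no response to hepatectomy was computed. The labels do not say whether each library came from a separate mouse. If they did not, the p-values measure only the spread between these libraries.

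Per the labels' protocols, RNA was extracted from frozen tissue with Trizol and a miRNeasy kit and libraries were made with standard Illumina or Nugen protocols. Whether the libraries kept strand is not given in the sources used here. The submitters' processing notes name TopHat and edgeR and the builds mm9 and mm10, without roles. Per the file headers, the deposited values are FPKM (fragments per kilobase of transcript, scaled to mapped fragments) as the authors deposited them, per gene locus and library. The locus positions are on mm10. The layout, with a locus field and a LOWDATA status, is the one that Cufflinks writes for gene tracking. No column other than those of the 6 libraries holds sample values. FPKM divides by transcript length and by library total, so a change in a few abundant transcripts shifts all other values of that library. It also divides reads among overlapping or near-identical gene models by estimation, so values of such models are uncertain. The file describes its loci as filtered, and the criterion is not given in the sources used here.

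The table holds 23847 loci, of which 312 carry LOWDATA in all 6 libraries and were left out, leaving 23535. Values of 0 are listed as 0.001 and were set to 0 before the logarithm. The table holds no mitochondrially encoded genes. Of all symbols, 254 occur at more than 1 locus, and 27 symbols are dates of the kind a spreadsheet makes from gene names. Symbols and positions are given as in the file, with positions counted from 1.

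Values were analysed as log2(FPKM + 1), so that a log2 difference understates the change of a gene near or under 1 FPKM. Genes with a mean FPKM of at least 1 over the 6 libraries were tested (10956 loci). KO was compared with WT in limma 3.58.1 (R 4.3.3; lmFit, and eBayes with a mean-variance trend), two-sided, with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. No rescaling between libraries was made in the primary analysis. Single values, such as a list score, were compared with an exact permutation test over the 20 assignments of 3 libraries to KO, whose smallest possible p is 0.1.

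A set of 35 gene lists covering liver functions, cell types, sex-biased genes, the clock and RNA quality was fixed before the data were examined. Of their 1105 distinct symbols, 7 were matched through a synonym in RefSeq GRCm38.p6. Lists with at least 5 tested members entered limma's camera (preset correlation between genes 0.01), which compares a list with all other tested genes, with adjustment over the 31 lists tested. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved on balance one way, or changed in either direction. For each list the number of members past 0.05 is also given adjusted over the list alone. The 4 lists with fewer than 5 tested members were T and NK cells (0 members), B and plasma cells (0), tissue from muscle, fat or pancreas (2) and mitochondrially encoded genes (0). List scores per library are medians of log2(FPKM + 1) after subtracting each gene's mean over the 6 libraries.

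The rule for named genes was also fixed before the data were examined. It takes Arid1a, the 10 highest and 10 lowest log2 differences among called genes whose KO values all lie on one side of the WT values, and the smallest p in that direction where fewer than 10 passed. Predicted or unnamed loci (symbols starting with Gm, LOC, Mir, Snor or a clone prefix with digits, ending in Rik, or holding several symbols) were left out of the naming only. It takes up to 4 members with the smallest p from each list described, and up to 2 from the lists of other cell types, sex, clock and RNA quality. Genes outside it are said to be chosen after their values were seen.

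Total read numbers are not given in the sources used here. Genes under 0.3 FPKM hold only a few reads, and the ratio of their values between libraries then clusters at ratios of whole numbers. With a tolerance of 0.02 on the log2 scale and up to 6 reads, 61.4% to 67.7% of such ratios to WT replicate 1 lay on a whole-number ratio, against 14.9% to 15.8% after shifting them. The depth relative to WT replicate 1 estimated this way was 1.20 and 1.21 in WT replicates 2 and 3 and 1.08, 1.03 and 0.834 in KO replicates 1, 2 and 3. Absolute depth is unknown, so no counting interval is given.

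The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, median-of-ratios rescaling, quantile normalization, a prior variance without trend, array weights, the replicate number as a block, each library left out, and calls that also needed a 1.5-fold difference. Exact matching of list symbols was added after seeing the data. The fit was tested on simulated data for the 10956 genes of this comparison, with 200 changed genes in each of 10 simulations. The changed genes were drawn only from those with a mean log2(FPKM + 1) over 2, and the folds are on that scale. Recovery of genes with lower expression was therefore not measured. It recovered 29.9% of genes changed 2-fold, 85.7% of those changed 4-fold and 95.8% of those changed 8-fold, with 7.90 false calls among 148 calls on average. Without changed genes it made 0.1 calls on average. At an unadjusted p under 0.05, camera found a list of 30 genes shifted by 0.5 on the log2 scale in 20 of 20 simulations. It found an unshifted list in 0 of 20. The simulated genes varied independently of each other. These rates therefore do not carry over to lists whose genes vary together, such as mitosis and G2/M, with an estimated correlation of 0.943.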

Results

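The transcript levels of 6 mouse livers were available at 40 h after partial hepatectomy, the surgical removal of most of the liver, after which the remaining hepatocytes re-enter the cell cycle. In 3 livers Arid1a was intact (WT), and in 3 it was deleted in hepatocytes by Alb-cre (KO). Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. FPKM summed to between 409150 and 495217 per library. Between 14874 and 15287 loci were listed above the floor of the table in each library. The 50 most abundant genes took between 39.8% and 46.1% of the summed FPKM. Relative depth ranged from 0.834 in KO replicate 3 to 1.21 in WT replicate 3, with WT replicate 1 as 1, and absolute depth is unknown. Xist lay between 84.6 and 115 FPKM in all 6 libraries, and the Y-linked genes Eif2s3y, Kdm5d and Uty were at the floor of 0.001 in all 6. Ddx3y, also Y-linked, was 0.00969 in KO replicate 2 and at the floor in the other 5.

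Arid1a (chromosome 4, 133679008 to 133753611, mm10) was 8.68, 8.45 and 8.49 FPKM in the WT libraries and 4.41, 5.57 and 6.15 in the KO libraries. Every library labelled KO lay below every library labelled WT. The mean was 8.54 ± 0.121 in WT and 5.38 ± 0.882 in KO (SD, n = 3 each), a log2 difference of -0.59 (SE 0.15). The exact two-sided permutation p was 0.1, the smallest this design allows, and limma's adjusted p was 0.207. The transcript was therefore not past the threshold in KO. Liver cells without Alb-cre keep the gene, and the table gives 1 value per locus with no separate value for the deleted exons.

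The comparison of KO with WT asks which transcripts differ in regenerating liver without Arid1a in its hepatocytes. Of 10956 genes tested, 13 passed an adjusted p of 0.05. In KO, 2 were higher and 11 lower, and for all 13 the KO libraries lay entirely on one side of the WT libraries. The called genes that fell encode bile acid and scavenger transport proteins, complement C4, E-cadherin and several enzymes. Sdr9c7, a short-chain dehydrogenase/reductase, had the lowest log2 difference, -3.26 (SE 0.26, adjusted p = 0.0302), with 17.3, 23.7 and 16.0 FPKM in WT and 1.13 ± 0.596 in KO (SD, n = 3). Slc10a2, the apical sodium-dependent bile acid transporter, was 12.2, 17.6 and 12.4 FPKM in WT and 1.97 ± 0.630 in KO (log2 difference -2.34, SE 0.21, adjusted p = 0.0302). Clmn, which encodes calmin, had the smallest adjusted p, 0.0245. Its mean FPKM in WT was 7.26 times that in KO, which was 1.38 ± 0.314, a log2 difference of -2.22 (SE 0.15).

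Cdh1, which encodes E-cadherin, was 10.5 ± 3.99 FPKM in WT and 1.28 ± 0.186 in KO (log2 difference -2.28, SE 0.26, adjusted p = 0.0488). Scara5, a scavenger receptor that binds ferritin, was 3.39 ± 0.616 in WT and 0.0776 ± 0.0549 in KO (log2 difference -2.02, SE 0.18). Pde9a, a cyclic GMP phosphodiesterase, was 3.14 ± 0.440 FPKM in WT, and in KO it was at the floor in replicates 1 and 3 and 0.0926 in replicate 2. Prtn3, which encodes proteinase 3 and overlaps another locus of the table, was 9.59, 8.48 and 6.90 FPKM in WT. In KO it was at the floor in replicates 1 and 2 and 0.970 in replicate 3. Dnajc12, an HSP40 family co-chaperone, went from 65.9 ± 5.63 to 16.9 ± 4.08 FPKM (log2 difference -1.92, SE 0.20). The complement genes C4b and C4a were 291 ± 10.4 and 45.6 ± 0.175 FPKM in WT and 60.3 ± 20.7 and 9.55 ± 3.21 in KO. They are near-identical neighbours on chromosome 17, so the division of reads between them is uncertain and the pair counts as 1 signal. Rnf39, the remaining called gene, named after its values were seen, was 3.19 ± 0.203 in WT and 0.414 ± 0.0789 in KO.

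The 2 called genes that were higher in KO were Vmo1 and Wbp5. Vmo1 was 1.34 ± 0.351 FPKM in WT and 6.34 ± 0.883 in KO (log2 difference 1.65, SE 0.18, adjusted p = 0.0421). Wbp5, on chromosome X, was 16.7 ± 0.797 and 45.7 ± 5.55 (log2 difference 1.40, SE 0.15, adjusted p = 0.0435). Among genes higher in KO, the next 8 by p under the naming rule were Marcksl1-ps4, Abcc4, Cdhr2, St3gal2, Ccl9, Pdgfa, Bex1 and Stap1, and all 8 missed the threshold, with adjusted p from 0.0594 to 0.0957. Among them, Abcc4, a basolateral export pump for bile acids and cyclic nucleotides, was 0.436 ± 0.0778 FPKM in WT and 3.73 ± 1.19 in KO. Cdhr2, a brush border protocadherin, was 0.242 ± 0.0960 and 5.78 ± 2.66. The chemokine gene Ccl9 was 11.4 ± 1.37 and 26.1 ± 1.76. Pdgfa, a growth factor gene, was 1.52, 2.72 and 1.80 in WT and 7.12, 8.14 and 5.74 in KO. Marcksl1-ps4 is a pseudogene, and its reads are uncertain.

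**Figure D1:**
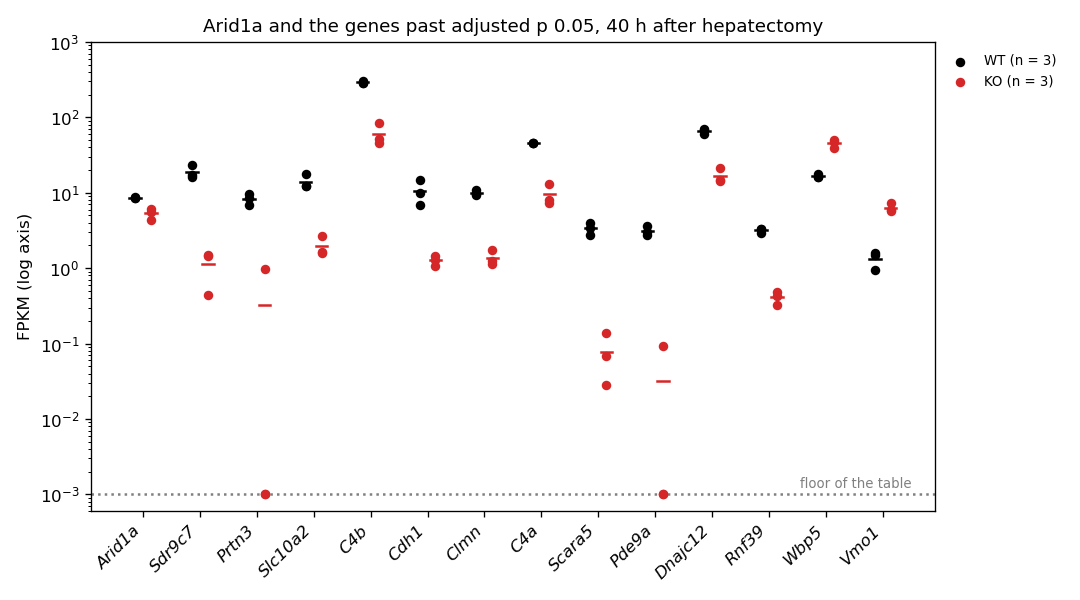
FPKM on a log axis of Arid1a and of the 13 genes past an adjusted p of 0.05 at 40 h after hepatectomy. Points are single libraries (WT black, KO red, n = 3 each), short lines are group means without an error bar, and the dotted line is the floor of the table at 0.001 FPKM. Arid1a lies between 8.45 and 8.68 in WT and between 4.41 and 6.15 in KO.

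The log2 differences of the 13 called genes kept their direction with any 1 library left out. Among them, Cdh1 ranged from -2.52 to -2.02, Clmn from -2.32 to -2.15, Rnf39 from -1.61 to -1.52 and Vmo1 from 1.52 to 1.73. The number of genes past the threshold did depend on single libraries, and what changed it was not tested. Without WT replicate 1 the count was 0 (940 genes at an unadjusted p under 0.05), without WT replicate 2 or KO replicate 3 it was 2, without WT replicate 3 it was 3, and without KO replicate 2 it was 242, of which 197 were higher in KO. At an unadjusted p under 0.05, 1231 genes were higher and 437 lower in KO, against 547.8 expected by chance in all. After median-of-ratios rescaling these became 586 and 733, and the calls 1 higher and 15 lower. After quantile normalization they became 554 and 764, and the calls 0 higher and 14 lower. The median log2 difference of all genes was 0.15 as deposited and 0.02 after median-of-ratios rescaling, so list medians are given relative to the median of all tested genes. The list scores of single libraries are not. On their scale the median of all genes was -0.106, -0.0763 and -0.021 in WT replicates 1, 2 and 3 and 0.0507, 0.093 and 0.05 in KO replicates 1, 2 and 3. KO and WT libraries did not overlap for 22.1% of tested genes, where chance gives 10%. Of these genes 1828 were higher and 596 lower in KO. The share is from values as deposited, so it includes the shift of all genes, and it is not given after rescaling.

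Of 31 gene lists, 20 differed from the other genes at an adjusted p under 0.05, 6 upward and 14 downward. None of the 20 held with a correlation estimated from the data, where the smallest adjusted p was 0.342, and fry, which tests whether a list moves on balance one way, gave 0 lists (smallest adjusted p 0.102; 5 lists at an unadjusted p under 0.05). For change in either direction fry gave 13 lists. With the preset correlation, camera also passed 9 to 17 lists when the libraries were divided into 3 and 3 so that KO and WT were mixed. Only 2 called genes belong to a list, C4b to the acute-phase list and Cdh1 to the periportal list.

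Mitotic genes stood highest. The 55 genes of the mitosis and G2/M list had a median log2 difference 1.78 above all genes (camera adjusted p = 6.80e-08, adjusted p = 0.598 with an estimated correlation). None was called, and 0 passed when adjusted over the list alone. The list score was -1.21, -1.37 and -0.19 in WT and 1.74, -1.23 and 2.36 in KO, so KO replicate 2 lay within the WT range and the exact permutation p was 0.3. With 1 library left out the list median ranged from 1.10 to 2.89, and without KO replicate 2, 40 genes of the mitosis and S phase lists were called, all higher in KO. Tubb5, a beta-tubulin gene, was 41.9 ± 14.3 FPKM in WT and 112 ± 30.4 in KO. The centromere histone gene Cenpa was 2.28 ± 0.996 and 14.2 ± 10.6. Ube2c, which encodes a conjugating enzyme of the anaphase-promoting complex pathway, was 4.51, 1.22 and 4.49 in WT and 65.2, 3.08 and 117 in KO. Cks2 was 13.6 ± 5.54 and 32.5 ± 16.6. Mki67, the proliferation marker, chosen after its values were seen, was 1.82, 1.43 and 6.98 FPKM in WT and 41.6, 1.57 and 66.7 in KO.

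The 51 genes of the DNA replication and S phase list had a median 0.57 above all genes (adjusted p = 0.000223, adjusted p = 0.669 with an estimated correlation), and 0 passed when adjusted over the list alone. Without WT replicate 2 the list was no longer past the threshold. Its score was -0.65, -1.07 and 0.58 in WT and 0.57, -0.20 and 0.61 in KO. Ccne1, which encodes cyclin E1, was 2.26 ± 1.44 FPKM in WT and 6.23 ± 1.14 in KO, with every KO library above every WT library. Orc6 was 2.39 ± 1.42 and 5.01 ± 1.27, Ccne2 was 1.04 ± 1.26 and 2.67 ± 0.659, and the thymidine kinase gene Tk1 was 6.95 ± 4.67 and 18.2 ± 10.4. KO replicate 2 also stood apart on the second principal component, which carried 27.3% of the variance.

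In the p53 and CDK inhibitor list, 19 genes lay above the median log2 difference of all genes and 3 at or below it. The list scores separated all KO from all WT libraries. The 22 genes had a median 0.56 above all genes (adjusted p = 1.76e-05, adjusted p = 0.431 with an estimated correlation). None was called over all genes, and 9 passed, all higher in KO, when adjusted over the list alone. The apoptosis-related genes Aen and Bax were 8.99 ± 1.80 and 12.5 ± 1.98 FPKM in WT and 18.9 ± 2.06 and 23.9 ± 3.24 in KO. Phlda3 was 0.963 ± 0.523 and 10.3 ± 6.24, and the cyclin gene Ccng1 was 8.68, 9.10 and 18.7 in WT and 42.1, 26.5 and 42.1 in KO.

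The 13 fetal liver and oncofetal genes had a median 0.89 above all genes (adjusted p = 0.00724, adjusted p = 0.342 with an estimated correlation). Of the 28 symbols of this list that were found, 13 passed the filter. It uses the mean of all 6 libraries, so a gene can pass through its KO values alone, as Bex1 did. With no filter, which lets in members of low expression, the median was 0.25, so its size depended on the filter. Over the list alone 4 passed, all higher in KO. Afp, alpha-fetoprotein, was 1.79, 1.73 and 2.88 FPKM in WT and 16.4, 59.9 and 9.19 in KO. Lpl, lipoprotein lipase, was 2.85 ± 1.14 and 18.6 ± 7.62, and Akr1b8, an aldo-keto reductase gene, was 1.24 ± 0.520 and 3.58 ± 0.925. Bex1 was at the floor in WT replicates 1 and 3 and 0.111 in WT replicate 2, against 1.36, 2.40 and 2.16 in KO. The 30 interferon response genes had a median 0.46 above all genes (adjusted p = 7.93e-06, adjusted p = 0.342 with an estimated correlation), and 0 passed over the list alone. Oasl1 was 1.06 ± 0.301 and 4.44 ± 1.82 FPKM, Ifit1 1.38 ± 0.501 and 4.69 ± 2.34, Stat2 12.5 ± 0.806 and 18.5 ± 1.45, and Gbp7 2.51 ± 0.978 and 5.33 ± 1.14 in WT and KO (SD, n = 3 each). For both lists the scores separated KO from WT.

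The 78 cytosolic ribosomal protein genes had a median 0.29 above all genes (adjusted p = 0.000155, adjusted p = 0.669 with an estimated correlation). The score was 0.77 in KO replicate 2 and between -0.45 and 0.10 elsewhere, and without KO replicate 2 the list was no longer past the threshold. Over the list alone 0 genes passed. Rps20 was 203 ± 42.4 FPKM in WT and 389 ± 184 in KO, Rpl22 was 29.4 ± 5.09 and 45.1 ± 11.7, and Rpl30 was 6.67 ± 0.919 and 17.5 ± 8.51. Rpl34 was 113 ± 15.2 and 35.8 ± 43.9, and its model overlaps that of Rpl34-ps1, so its reads are uncertain.

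Cholesterol biosynthesis and pericentral genes were the lists furthest below the other genes by p. The 26 cholesterol genes had a median log2 difference -0.81 relative to all genes (adjusted p = 7.41e-10, adjusted p = 0.431 with an estimated correlation), and 0 passed over the list alone. Sqle, squalene epoxidase, was 55.0 ± 7.20 FPKM in WT and 25.5 ± 11.6 in KO, Lss 22.8 ± 4.08 and 11.2 ± 6.47, Mvk 23.4 ± 6.88 and 12.6 ± 4.03, and Sc4mol 133, 96.9 and 136 in WT and 89.5, 22.5 and 46.9 in KO. The list score was 0.34, -1.03 and -0.16 in KO replicates 1, 2 and 3, the first within the WT range of 0.13 to 0.50, and without KO replicate 2 the list median was -0.38. Pericentral hepatocytes surround the central vein of the lobule. Their 25 genes had a median -0.60 relative to all genes (adjusted p = 6.80e-08, adjusted p = 0.342 with an estimated correlation), and with 1 library left out the median ranged from -1.08 to -0.36. The scores of all KO libraries lay below those of all WT libraries, by a narrow margin (-0.0638 in KO replicate 1 and -0.0576 in WT replicate 2), and 6 genes passed over the list alone, all lower in KO. The glutamate transporter gene Slc1a2 was 14.3 ± 7.71 FPKM in WT and 1.46 ± 1.15 in KO, the Wnt antagonist gene Notum was 15.6, 15.6 and 23.8 in WT and 7.47, 2.56 and 4.97 in KO, and the dicarboxylate transporter gene Slc13a3 was 22.4 ± 6.11 and 5.76 ± 2.91.

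The 25 periportal genes had a median -0.08 relative to all genes and did not pass (adjusted p = 0.215), although they did without KO replicate 3 (-0.19, adjusted p = 0.0169). Over the list alone 2 passed in opposite directions, Cdh1 and Hsd17b13, a lipid droplet protein gene that was 72.6 ± 37.7 FPKM in WT and 234 ± 72.3 in KO. Of 47 cytochrome P450 and xenobiotic genes, 6 passed as higher and 3 as lower over the list alone, and the list median was -0.40 relative to all genes (adjusted p = 0.00411, adjusted p = 0.669 with an estimated correlation). Ephx1, microsomal epoxide hydrolase, was 84.7 ± 26.1 and 201 ± 15.4 FPKM in WT and KO, and the carboxylesterase gene Ces2a was 11.9 ± 3.31 and 28.3 ± 6.80. Cyp2e1 was 1681 ± 767 and 441 ± 157, and Ces3a was 136 ± 12.3 and 30.1 ± 16.0. This list also lost its call after either rescaling and without KO replicate 2, where its median was 0.02 relative to all genes.

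Plasma protein and acute-phase genes were lower as lists. For 47 secreted plasma proteins the median was -0.34 relative to all genes (adjusted p = 1.67e-06, adjusted p = 0.342 with an estimated correlation), and 0 passed over the list alone. Without KO replicate 2 the median was -0.16, and the score of KO replicate 1, 0.0893, lay within the WT range of 0.0115 to 0.17. Fetub was 253 ± 4.48 FPKM in WT and 115 ± 27.7 in KO, Igfals 42.1 ± 1.44 and 27.1 ± 1.56, Apoc4 1139 ± 237 and 712 ± 89.3, and Apoc2 444 ± 82.6 and 1117 ± 638. For 35 acute-phase genes the median was -0.47 (adjusted p = 8.24e-05, adjusted p = 0.431 with an estimated correlation), with 2 members higher and 1 lower over the list alone, and the call was lost after quantile normalization. The score was 0.52 in WT replicate 1 and between -0.24 and 0.0436 in the other 5 libraries, and without WT replicate 1 the median was -0.23. The serpin genes Serpina3n and Serpina3g, with near-identical relatives beside them, were 696 ± 320 and 17.9 ± 5.39 FPKM in WT and 1899 ± 124 and 60.4 ± 19.7 in KO. C4b was the lower one. Orm3 was 6.51 ± 3.32 and 1.64 ± 0.829.

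Further metabolic lists were lower by smaller amounts. The median was -0.27 relative to all genes for 39 fatty acid oxidation genes (adjusted p = 0.000159, adjusted p = 0.598 with an estimated correlation), -0.22 for 37 urea cycle and amino acid genes (adjusted p = 0.000514, adjusted p = 0.538 with an estimated correlation), -0.28 for 30 lipogenesis genes (adjusted p = 0.00630, adjusted p = 0.342 with an estimated correlation) and -0.30 for 25 bile acid genes (adjusted p = 0.0398, adjusted p = 0.538 with an estimated correlation). It was -0.11 for 31 TGF-beta pathway genes (adjusted p = 0.0180, adjusted p = 0.342 with an estimated correlation) and -0.10 for 31 hepatocyte transcription factors (adjusted p = 0.0260, adjusted p = 0.509 with an estimated correlation). Over the list alone, Pparg among the lipogenesis genes passed (4.75 ± 1.13 FPKM in WT and 0.981 ± 0.703 in KO), as did Inhbc, an inhibin beta subunit, in the TGF-beta list (51.1 ± 10.4 and 13.3 ± 3.93) and, in the opposite direction to its list, Abcc4 among the bile acid genes (0.436 ± 0.0778 and 3.73 ± 1.19). The ornithine aminotransferase gene Oat was 247 ± 117 and 59.4 ± 23.4, and Prodh 15.8 ± 7.05 and 5.38 ± 0.699. Thrsp was 28.2, 4.25 and 16.0 in WT and 4.80, 1.96 and 3.56 in KO, Abcc3 15.8 ± 5.94 and 5.17 ± 3.18, and Tgfbr2 4.60 ± 0.660 and 6.73 ± 1.05. These 6 lists each lost the call under at least 1 rescaling, filter or left-out library. The urea cycle median was 0.0479 without KO replicate 2, the fatty acid oxidation median -0.00942 without KO replicate 3, and the bile acid list, with a median of -0.13 without WT replicate 3, kept its call in 7 of 15 settings.

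Lists did not pass for 23 SWI/SNF subunits (median 0.10 relative to all genes, adjusted p = 0.109), 25 gluconeogenesis and glycogen genes (0.08, adjusted p = 0.662), 27 immediate-early and growth response genes (0.08, adjusted p = 0.735) and 30 unfolded protein and integrated stress response genes (0.43, adjusted p = 0.556). For gluconeogenesis and immediate-early genes the direction of the test was opposite to the sign of the median. The stress response score was 0.99 in KO replicate 2, -0.0685 and -0.0243 in KO replicates 1 and 3 and between -0.36 and -0.0955 in WT. The SWI/SNF score was between 0.0916 and 0.14 in KO and between -0.24 and -0.00332 in WT. Both separated KO from WT in the values as deposited. For the stress response, WT replicate 2 (-0.0955) and KO replicate 1 (-0.0685) differed by less than the medians of all genes there (-0.0763 and 0.0507). Its separation is therefore not particular to the list. Among SWI/SNF subunits, Phf10 was 7.43 ± 1.25 FPKM in WT and 11.9 ± 0.938 in KO. Ugp2, which makes UDP-glucose, passed over its list alone (32.3 ± 7.63 and 75.2 ± 11.9), and the glycogen branching enzyme gene Gbe1 was 13.9 ± 0.746 and 19.7 ± 3.41. Egfr, the epidermal growth factor receptor gene, was 196 ± 20.9 and 88.1 ± 34.4, and Atf3 was 0.732 ± 0.206 and 1.79 ± 0.113.

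Markers of other liver cell types did not pass as lists in the primary analysis. The median relative to all genes was 0.14 for 9 cholangiocyte genes (adjusted p = 0.368), -0.07 for 27 macrophage genes (adjusted p = 0.735), 0.00 for 31 sinusoidal endothelial genes (adjusted p = 0.975), -0.20 for 29 stellate cell and matrix genes (adjusted p = 0.215), 0.07 for 5 neutrophil genes (adjusted p = 0.737) and -0.60 for 9 erythroid genes (adjusted p = 0.128). The test's direction was opposite to the median's sign for the endothelial and neutrophil lists. With 1 library left out, 3 of these lists passed as lower, macrophage genes without KO replicate 1 (-0.29, adjusted p = 0.01001), stellate genes without WT replicate 3 (-0.27, adjusted p = 0.0106) and erythroid genes without KO replicate 3 (-1.24, adjusted p = 0.00129). Erythroid genes also passed with the replicate number as a block (adjusted p = 0.0480). Marco was 7.98 ± 2.52 FPKM in WT and 18.7 ± 8.06 in KO, Tyrobp 5.69 ± 3.10 and 9.67 ± 0.617, Reln 9.63 ± 0.817 and 17.7 ± 3.75, Col4a1 8.60 ± 2.23 and 16.4 ± 2.65, Pkhd1 0.840 ± 0.495 and 1.90 ± 0.449, and Wwc1 20.2 ± 1.53 and 27.8 ± 4.35.

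Sex-biased and clock genes differed as lists, although Xist was high and Y-linked genes were at or near the floor in all libraries. For 32 loci of female-biased liver genes the median was -0.92 relative to all genes (adjusted p = 1.67e-06, adjusted p = 0.342 with an estimated correlation), with 2 members higher and 3 lower over the list alone. Its score was -0.99 in KO replicate 2 and 0.33 in KO replicate 1, within the WT range of 0.17 to 0.45, and without KO replicate 2 the median was -0.33. For 17 male-biased genes it was -0.56 (adjusted p = 0.000527, adjusted p = 0.342 with an estimated correlation), with 3 lower over the list alone, and the call was lost without KO replicate 2. Sult3a1, a female-biased sulfotransferase gene, was 36.4, 6.87 and 109 FPKM in WT and 0.0915 or at the floor in KO. Nipal1 was 7.22 ± 2.55 and 17.2 ± 2.99. Cyp2u1 was 3.30 ± 0.302 and 0.801 ± 0.597, and Mup7, one of a family of near-identical genes, was 75.0, 8.80 and 42.5 in WT and 3.78, 0.0370 and 1.24 in KO. For 22 clock genes the median was -0.50 (adjusted p = 0.00171, adjusted p = 0.342 with an estimated correlation), and 0 passed over the list alone. Without WT replicate 1 it was -0.18. Tspan4 was 42.0 ± 3.69 and 26.3 ± 3.72, and Por, also a member of the cytochrome P450 list, 184 ± 61.0 and 99.3 ± 17.3. Of the 22 clock genes, 7 lay above the median log2 difference of all genes and 15 at or below it. Only 3 had an unadjusted limma p under 0.05, all lower in KO, and the list scores of KO and WT overlapped. A shift of the clock cannot be read from these values.

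**Figure D2:**
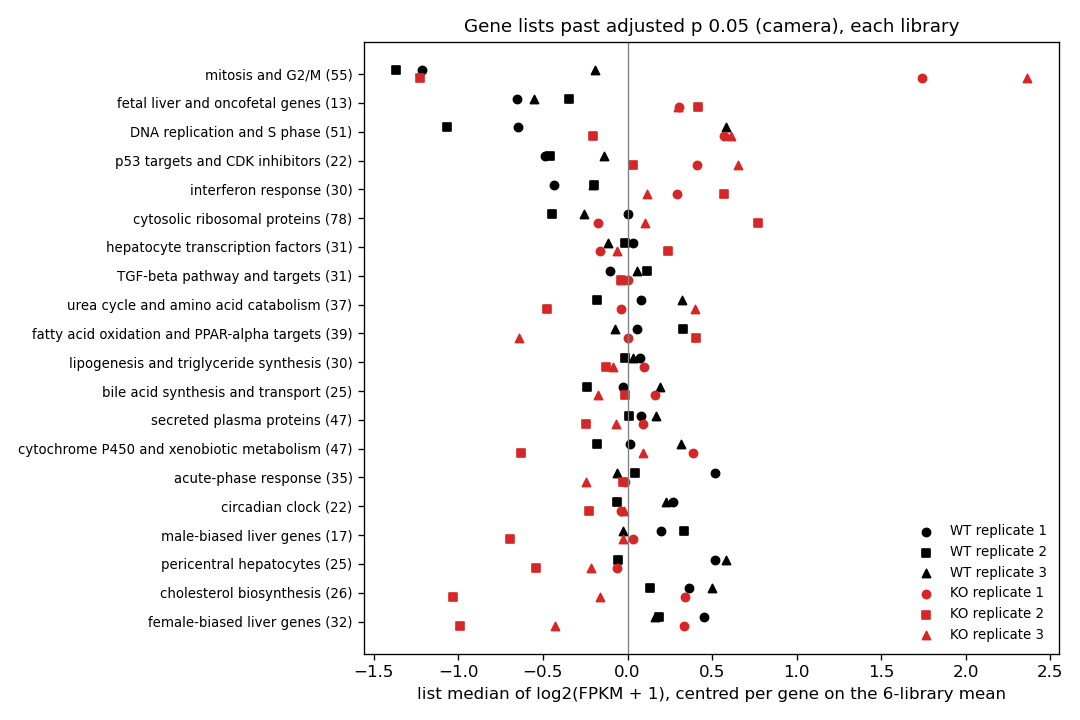
Score of each gene list past an adjusted p of 0.05 in each library, as the list median of log2(FPKM + 1) after subtracting each gene's mean over the 6 libraries (horizontal axis), with the number of tested genes in brackets. Black symbols are WT and red symbols KO livers, 1 symbol shape per replicate. The mitosis score is 1.74 and 2.36 in KO replicates 1 and 3 and -1.23 in KO replicate 2.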

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

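Of the alternatives, exact symbol matching was chosen after seeing the data, and it left 20 lists past the threshold. The count of 13 genes was 12 to 18 with other pseudocounts, either rescaling, no variance trend or a 1.5-fold requirement. It was 6 with no filter and 5 with a mean of at least 5 FPKM, where the number of genes tested and the fitted variance change, and 29 with array weights, for which the cause was not tested. With 1 library left out it ranged from 0 to 242. Of the 13 genes, 0 were called again without WT replicate 1, 2 or 3, 6 without KO replicate 1, 2 without KO replicate 3 and all 13 without KO replicate 2. The count with the replicate number as a block was 47, of which 10 were among the 13. Whether the numbers pair the libraries cannot be decided from 3 libraries per group. Same-numbered deviations from the group means correlated at -0.08, 0.16 and 0.16, and 1 of 3 WT and 2 of 3 KO libraries correlated best with their own number. The block gave 21 lists. The count of 20 lists was 0 with an estimated correlation and 0 with fry, and 13 to 20 with 1 library left out, lowest without KO replicate 2. Across the 15 settings that refit the genes, 9 of the 20 lists passed in each one they could be tested in. Arid1a lay between -0.76 and -0.48 in log2 difference, never past the threshold (adjusted p 0.102 to 0.546). Of 105 named loci, 104 kept their direction in all settings. C1qa ranged from -0.00651 to 0.32 with 1 library left out.

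The values below are list medians relative to all genes. With an estimated correlation, and with fry, the medians stay as they are and none of the 20 passed: S phase 0.57, mitosis 1.78, p53 0.56, interferon 0.46, fetal 0.89, ribosomal 0.29, TGF-beta -0.11, hepatocyte factors -0.10, cytochrome P450 -0.40, bile acid -0.30, cholesterol -0.81, lipogenesis -0.28, fatty acid oxidation -0.27, urea cycle -0.22, plasma proteins -0.34, acute-phase -0.47, pericentral -0.60, male-biased -0.56, female-biased -0.92 and clock -0.50. Calls were lost, for causes not tested, as follows. With no filter these were TGF-beta -0.0305, hepatocyte factors -0.0221, bile acid -0.20 and lipogenesis -0.19, and at 5 FPKM TGF-beta -0.10. With median-of-ratios rescaling they were cytochrome P450 -0.42 and bile acid -0.32. With quantile normalization they were cytochrome P450 -0.40, bile acid -0.26, lipogenesis -0.28 and acute-phase -0.27. With array weights they were cytochrome P450 -0.17, bile acid -0.12 and ribosomal 0.10. The fetal list kept its call, with a median of 0.25 with no filter and 1.22 with a pseudocount of 0.1. With the block, erythroid genes passed at -0.60. With 1 library left out, periportal, macrophage, stellate and erythroid genes each passed once, as lower in KO.

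The test's direction turned for lists that had not passed and, without KO replicate 2, for cytochrome P450, and the cause was not tested. With no filter it turned for gluconeogenesis at 0.16, immediate-early at 0.0715 and endothelial genes at 0.0817. At 5 FPKM it turned for immediate-early at 0.0748, stress response at 0.37, macrophage at -0.00551 and endothelial genes at -0.0313. With median-of-ratios rescaling it turned for immediate-early at 0.0619 and neutrophil genes at 0.0475, and with quantile normalization for gluconeogenesis at 0.0877, immediate-early at 0.0705 and neutrophil genes at 0.0898. With array weights it turned for stress response at 0.0821 and macrophage genes at 0.0187, and with the block for endothelial genes at 0.00129. With fry, which compares with 0 and not with other genes, it turned for gluconeogenesis at 0.0793, immediate-early at 0.0799, periportal at -0.0785, macrophage at -0.0681, endothelial at 0.00129, stellate at -0.20 and neutrophil genes at 0.0690. With 1 library left out the medians ranged from 1.10 to 2.89 for mitosis, -1.13 to -0.38 for cholesterol, -1.08 to -0.36 for pericentral, -1.11 to -0.33 for female-biased, -0.50 to -0.18 for clock, -0.41 to -0.16 for plasma protein, -0.54 to -0.23 for acute-phase, 0.46 to 0.79 for p53, 0.38 to 0.62 for interferon, 0.60 to 0.96 for fetal, -0.0412 to 0.20 for cholangiocyte, 0.0243 to 0.15 for SWI/SNF, 0.24 to 1.10 for S phase, -0.25 to -0.0630 for TGF-beta, -0.40 to -0.13 for bile acid, -0.65 to 0.0225 for cytochrome P450, 0.0612 to 0.49 for ribosomal, -1.24 to -0.23 for erythroid, -0.48 to -0.00942 for fatty acid oxidation, -0.0447 to 0.0955 for gluconeogenesis, -0.27 to -0.0804 for stellate, -0.25 to -0.0841 for hepatocyte factor, -0.11 to 0.22 for immediate-early, -0.38 to -0.23 for lipogenesis, -0.11 to 0.15 for endothelial, -0.29 to 0.0741 for macrophage, -0.76 to -0.21 for male-biased, -0.56 to 0.45 for neutrophil, -0.19 to 0.17 for periportal, -0.00730 to 0.59 for stress response and -0.48 to 0.0479 for urea cycle genes. Comparisons with livers before hepatectomy and count-based tests were not run, because the table analysed holds FPKM of the 40 h livers. Absolute depth is unknown.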

Other observations

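All genes in these first paragraphs were chosen after their values were seen, and none passed an adjusted p of 0.05 with all 6 libraries in the primary analysis. Without KO replicate 2, 40 histone genes (symbols starting with Hist or H2af) and Gsta1, Gstm3, H19, Krt18 and H2-Q8 did, all higher in KO. H2-Q8 also did with a pseudocount of 0.1 and with array weights, and 2 histone genes did with the replicate block. Histone genes, many of whose transcripts accumulate in S phase, were higher in KO at all 61 tested loci with a Hist symbol. The median log2 difference was 1.77, and it was 1.63 after median-of-ratios rescaling and 1.62 after quantile normalization. KO and WT did not overlap at 24 of the 61 loci, where 22.1% of all tested genes did not overlap, and these loci vary together. Their score was 1.10 and 2.03 in KO replicates 1 and 3 and -0.47 in KO replicate 2, against -0.82, -1.30 and -0.50 in WT. KO replicate 2 and WT replicate 3 (-0.50) differed by less than the medians of all genes there (0.093 and -0.021). All 7 Gstm loci and 3 of 4 Gsta loci, encoding glutathione S-transferases, were higher in KO. Gstm3 was 14.2, 16.8 and 18.9 FPKM in WT and 127, 27.1 and 85.7 in KO, and Gsta1 was 0.404, 0.318 and 0.186 against 5.97, 0.546 and 6.08. The keratin genes Krt18 and Krt8 were 127 ± 12.6 and 103 ± 14.4 FPKM in WT and 313 ± 53.6 and 186 ± 30.8 in KO (SD, n = 3 each), with limma adjusted p of 0.108 and 0.193. The CDK inhibitor gene Cdkn1a was 17.5 ± 9.83 and 44.3 ± 4.81, and the imprinted gene H19 was 0.183, at the floor and 0.775 in WT and 8.97, 0.499 and 13.2 in KO.

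Major urinary protein (Mup) genes, a cluster of near-identical copies on chromosome 4, were lower in KO at 19 of 20 tested loci, with a median log2 difference of -3.99 (-4.11 after median-of-ratios rescaling and -4.01 after quantile normalization). KO and WT did not overlap at 15 loci. Reads cannot be assigned to single copies with certainty. Mup20 went the other way, at 4.29, 23.1 and 3.77 FPKM in WT and 102, 10.5 and 51.2 in KO. H2-Q8, a class I histocompatibility gene with close relatives beside it, had a log2 difference of 3.07 (adjusted p = 0.128).

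For the patterns that follow, the test of a mislabelled library on all 162 genes and the counts of splits were set before their results were seen, and the other tests, including that on the 45 lower genes, were chosen after. The 6 libraries can be divided into 3 and 3 in only 10 ways, too few for a share under 0.05. The real division gave 13 genes and the others, which mix KO and WT, 0 to 2. For lists the real division gave 20 and the others 9 to 17. Camera with the preset correlation thus passed many lists in divisions that mix KO and WT. In each case 1 of the 10 divisions, the real one, gave as many.

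The mitosis score was high in KO replicates 1 and 3 and within the WT range in KO replicate 2. Cdk1 was 0.833, 0.445 and 3.51 FPKM in WT and 15.1, 0.745 and 24.4 in KO, and Top2a and Ccnb1 followed the same pattern. Tubb5 and Cks2 did not, at 77.4 and 21.4 in KO replicate 2 against 32.9 to 58.4 and 7.38 to 18.1 in WT. The test set beforehand for a wrong label on KO replicate 2 used 162 genes outside the cell cycle called without that library. KO replicate 2 lay beyond all WT libraries on the KO side in 62.3% of them (exact binomial 95% interval 54.4% to 69.8% if genes varied independently). The share was past the preset bound of 60% against a wrong label, but its interval spans that bound, so the test weighs little. Arid1a, the deleted gene, was 5.57 FPKM in KO replicate 2, between KO replicates 1 and 3 (4.41 and 6.15) and below all WT libraries (8.45 to 8.68). The genes lower in KO, taken separately only afterwards, argue against a WT library like the other WT libraries. KO replicate 2 lay below all WT libraries in 97.8% of these 45 genes (lower bound 88.2% if genes varied independently). A WT library would do so in 25%, or at most 50% for closely spaced WT values. The median place of KO replicate 2 was 0.993 of the way from the WT mean to the other KO libraries (quartiles 0.681 and 1.18). For the 117 higher genes that place was 0.101, near WT. KO replicate 2 lay above all WT libraries in 57 of these 117, within the bound of 50% for a WT library. Genes of 1 library vary together, so a WT liver that departed widely from the other WT livers was left open. A rise in leukocyte number as large as that of the mitotic genes is argued against by 68 leukocyte markers. They differed from the WT mean by a median log2(FPKM + 0.1) of 0.40 in KO replicate 1 and -0.09 in KO replicate 3, while the mitotic genes differed by 3.56 and 4.31. Of the abundant markers, C1qa was 27.2 and 18.9 FPKM there against 14.7 to 23.5 in WT, and Lcn2, which hepatocytes also express, was 1411 and 1324 against 631 to 2330. Marco (16.9 and 11.8 against 5.11 to 9.84) and Tyrobp (9.70 and 10.3 against 3.24 to 9.18) lay above the WT range. Such markers follow the number of leukocytes and not their division. Dividing leukocytes, if already present or few, were therefore left open. A genotype effect on the number or timing of dividing cells, which may differ between livers at 1 time point, cannot be told apart from liver-to-liver variation, since the exact permutation p of 0.3 comes from 3 livers against 3.

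Of the 13 called genes, 4 lie between 31386234 and 36947986 on chromosome 17, in and around the histocompatibility complex (Pde9a, C4b, C4a and Rnf39), where 0.688 would be expected on the whole chromosome from its 5.29% of tested genes. C4a and C4b count as 1 signal. The bounds of the region were set by these genes after they were seen, so the expected number is no test of an excess. Chromosome 10 also holds called genes, further apart, Sdr9c7, Prtn3 and Dnajc12, which start at 127898535, 79879667 and 63382443. A candidate explanation is a strain variant in the mixed C57/B6 and 129 background that differs between the WT and KO mice. Of the 137 uncalled genes of the region, 21.2% separated KO from WT, against 22.1% of all tested genes. The exact binomial 95% interval was 14.7% to 29.0% if genes varied independently, and it is too narrow where they vary together. A variant that acts on a few genes would leave that share as it is, and H2-Q8, a class I gene in the region whose model overlaps another locus, was at the floor in all 3 WT libraries and at 17.4, 2.96 and 7.06 FPKM in KO, which a strain difference in this polymorphic family could also give, so a variant and a genotype effect on these genes cannot be told apart.

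Rpl34 was 128, 113 and 98.0 FPKM in WT and 14.7, 86.3 and 6.41 in KO, while Rpl34-ps1, whose model covers nearly the same positions on chromosome 3 in the table, was 88.9, 55.4 and 73.0 in WT and 184, 286 and 224 in KO. On log2 FPKM the KO minus WT differences were -2.48 and 1.68, and the summed FPKM differed by 0.48 (SE 0.30). The opposite shifts are consistent with reads of 1 locus divided differently between overlapping models. No biological explanation was tested for this pair, and what moved the division was not tested.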
